A study of Mus musculus with 8 samples.

How the data were processed

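RNA was extracted with TRIzol from mouse ES cells of the 129/Ola strain at 4 stages of cardiac differentiation, enriched for poly(A) RNA, fragmented, amplified by PCR and sequenced on an Illumina GAIIx, per the labels' protocols. The stages were ESC (day 0), MES (day 4), CP (day 5.3) and CM (day 10), each with 2 libraries that the series' design text calls biological duplicates. Reads were aligned with Novoalign 2.07.00 and the genome build was mm9, per the submitters' processing notes. The read counter, the annotation release, the filter on genes and whether and how the 2 libraries of a stage were combined are not given in the sources used here.

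The values are RPKM per the file headers, as deposited by the authors, with 1 column per stage and 1 entry per Ensembl gene ID. Each of the 13540 genes exceeds 1 RPKM in at least 1 stage (the lowest maximum is 1.00017), so genes below that at all stages were not analysed here, and a gene missing from a list cannot be called absent from the cells. Without replicate columns, the spread between replicates, replicate agreement and any test against that spread could not be had. The limma tests and the competitive gene set tests planned for 8 separate libraries were therefore not run, and the plan fixed for 1 value per stage was followed: log2 ratios of RPKM with a pseudocount of 1, and counts of genes at least 2-fold apart, as descriptions of these stage values.

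Depth was recovered from the low values. In 2238 genes with low values, the values of 91.0% lay on whole multiples of a common step in all stages (relative tolerance 5e-07) once 1 depth ratio per stage was set, against 0% with wrong depth ratios, so each column has a single depth, as either pooled reads of both libraries or a single library would give. Relative to ESC these depths were 0.822 for MES, 0.860 for CP and 1.18 for CM. The absolute depth came from exon lengths of GENCODE M21, whose build GRCm38 differs from that of the files, so no coordinates were used. It was set where the depths of single genes piled up, and 25.2% of 4980 genes lay within 0.1% of it. Depths were 75.3, 62.0, 64.8 and 88.5 M reads (1 M is 1000000) in ESC, MES, CP and CM. Reads were recovered for 5187 genes (38.3%) as the smallest whole numbers that give the values. A count of 3 reads on a 2 kb gene equals 0.0199, 0.0242, 0.0232 and 0.0169 RPKM in the 4 stages. For such a gene at 1 RPKM in MES, the 95% Poisson interval spans 83.2% to 119% of the value. Intervals and floors cover counting error only, since PCR copies of a molecule were not marked. In reads simulated for 1990 genes at lower expression than in the table, reads were recovered for 73.6%, and 100% of these were correct up to a common divisor. More genes were recovered there than in the table (38.3%), so accuracy at the table's own levels was not shown.

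Before the data were examined, 32 gene lists with 448 genes were fixed, of which 371 genes were in the table, 4 of them matched by gene ID because the table uses an older symbol. Each list is described by how many members were at least 2-fold higher or lower, by its median, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. In simulated lists of 15 genes for CM minus CP, no added shift put 5 of 100 lists above the 97.5th percentile and 3 below the 2.5th percentile, a shift of 0.5 put 62 above and a shift of 1 put 100 above. These simulated lists held genes drawn at random. Members of a fixed list may vary together, which neither this check nor the percentiles allow for.

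The rule for named genes was also fixed beforehand. For each of the 3 comparisons of adjacent stages it takes the 6 genes with the largest difference in each direction, leaving out names that are only clone or model numbers and replication-dependent histone genes. Of each list it takes up to 4 members of at least 2-fold difference and up to 2 others with the highest mean RPKM, and it takes 12 marker genes at every stage (Pou5f1, Nanog, T, Mesp1, Nkx2-5, Tbx5, Isl1, Gata4, Actc1, Myh6, Myh7 and Tnnt2). The condition in that rule that both libraries of a stage agree in direction could not be applied. Genes of the closing section outside this rule are named as such there. Shared sequence was measured as the percentage of the 32-base words of a gene's longest M21 transcript that occur in M21 transcripts of other genes. Of the genes examined it is over 50% in Nppa, Pln, Tagln, Dppa5a, Hspb1, Igf2, Cpt1b, Smarcd3, Hoxb3, Hoxd3, Pgk1, Eno1, Actg1, Lats2 and Hba-a1, whose levels are uncertain if the authors' counting split or dropped shared reads. The longest transcript can hold sequence that other transcripts of the gene lack, so sharing can be understated. Genes at 50% or less are therefore not free of this uncertainty. Strand was not used, so overlapping genes cannot be told apart.

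Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, a minimum of 4-fold, no filter, a minimum of 3 RPKM in at least 1 stage, and quantile normalization across stages. Scaling to the same upper quartile, scaling to the same sum of 1000000, and use of protein-coding genes only were added after seeing the data. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.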

Results

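Poly(A) RNA was sequenced at 4 stages of the directed differentiation of mouse embryonic stem cells of the 129/Ola strain into heart muscle cells. The stages were embryonic stem cells (ESC, day 0), mesoderm (MES, day 4), cardiac precursors (CP, day 5.3) and cardiomyocytes (CM, day 10), with 2 libraries per stage and 8 in all. Cells grew first as floating aggregates called embryoid bodies, were reaggregated with VEGF, Activin A and BMP4, and were then plated with VEGF, basic FGF and FGF10. The analysed table lists 13540 genes with 1 RPKM value per stage (reads per kilobase of gene model, scaled to depth). Whether a stage's value rests on both of its libraries or on 1 of them cannot be told from the table. It holds no separate values for the replicates, so the differences given here have no replicate check, no SD and no p-value. Depth was estimated from the steps between low values at 75.3 M reads (1 M is 1000000) for ESC, 62.0 M for MES, 64.8 M for CP and 88.5 M for CM. At these depths a gene model of 2 kb at 1 RPKM rested on 151 reads in ESC, 124 in MES, 129.6 in CP and 177 in CM.

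Pou5f1 and Nanog, transcription factors of the pluripotent state, were highest in ESC. Pou5f1 stood at 670.0, 76.4, 5.65 and 0.0429 RPKM in ESC, MES, CP and CM, and Nanog at 164, 4.84, 0.434 and 0.146 RPKM. T and Mesp1, transcription factors of the primitive streak and the earliest cardiac mesoderm, were highest in MES, at 53.2 and 148 RPKM, against 3.60 and 0.125 RPKM in ESC and 0.160 and 0.278 RPKM in CP. In CM, T was at 0.00489 RPKM and Mesp1 at 0.0620 RPKM. Among the cardiac transcription factors, Gata4 stood at 0.428 RPKM in ESC and already at 50.7 RPKM in MES, then at 53.2 RPKM in CP and 59.3 RPKM in CM. Isl1, a marker of second heart field progenitors, had its highest value in CP, with 0.142, 12.8, 49.9 and 14.3 RPKM over the 4 stages. Nkx2-5 stood at 0.941 and 1.30 RPKM in ESC and MES, and at 70.1 and 178 RPKM in CP and CM. Tbx5 went from 0.00831 and 0.440 RPKM to 10.0 and 18.8 RPKM. The contractile protein genes Actc1, Myh6, Myh7 and Tnnt2 were highest in CM, at 3917, 1614, 1053 and 1293 RPKM. In CP they stood at 352, 112, 106 and 437 RPKM, in MES at 6.07, 0.454, 0.624 and 0.116 RPKM, and in ESC at 3.68, 3.33, 0.534 and 0.155 RPKM. The longest transcripts of Myh6 and Myh7 share 31.8% and 37.9% of their 32-base words with transcripts of other genes. Reads could therefore have been split between close relatives. The Ensembl gene IDs of these 12 genes in the table are ENSMUSG00000024406 (Pou5f1), ENSMUSG00000012396 (Nanog), ENSMUSG00000062327 (T), ENSMUSG00000030544 (Mesp1), ENSMUSG00000015579 (Nkx2-5), ENSMUSG00000018263 (Tbx5), ENSMUSG00000042258 (Isl1), ENSMUSG00000021944 (Gata4), ENSMUSG00000068614 (Actc1), ENSMUSG00000040752 (Myh6), ENSMUSG00000053093 (Myh7) and ENSMUSG00000026414 (Tnnt2). The lowest values rest on few reads: the Pou5f1 value in CM corresponds to 5 recovered reads, with a 95% Poisson interval of 0.0139 to 0.10 RPKM that covers counting error only.

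**Figure D1:**
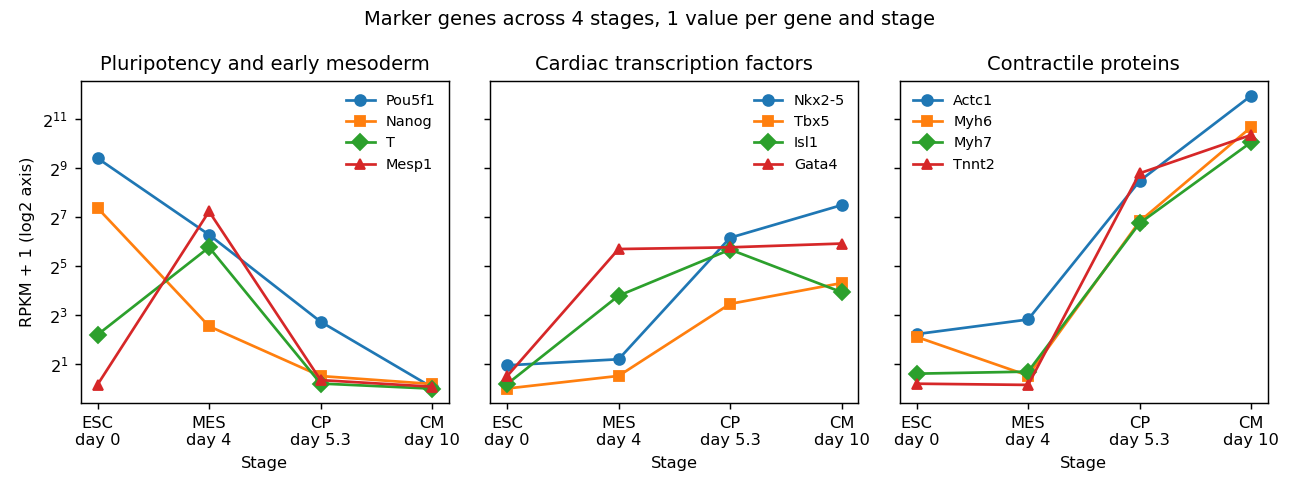
RPKM + 1 (log2 axis) of 12 marker genes at the 4 stages, in 3 panels for pluripotency and early mesoderm, cardiac transcription factors and contractile proteins, with 1 point per gene and stage and no error bars because the table gives 1 value per stage. Mesp1 and T peak in MES at 148 and 53.2 RPKM, and Actc1 reaches 3917 RPKM in CM.

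Counted over all 13540 genes on the log2(RPKM + 1) scale, which understates differences of genes with low values, 1498 genes were at least 2-fold higher and 1519 at least 2-fold lower in MES than in ESC. Which of these 2 numbers was larger depended on the settings, with 2273 higher and 2103 lower at a pseudocount of 0.1 and 376 and 470 at a minimum of 4-fold. In CP, 1207 genes were at least 2-fold higher than in MES and 529 lower. In CM, 1524 were at least 2-fold higher than in CP and 1729 lower, a balance that depended on the settings. It was 1683 higher and 1566 lower with quantile normalization across stages and 437 and 320 at a minimum of 4-fold, but 1937 and 2686 with a pseudocount of 0.1 and 1674 and 2799 with each stage scaled to a sum of 1000000, which also lessens the weight of the pseudocount. Across all 4 stages 8556 genes (63.2%) had a range of at least 2-fold, of which 2847 were highest in ESC, 1645 in MES, 1297 in CP and 2767 in CM. The Pearson correlation across genes was highest between MES and CP (0.89) and lowest between ESC and CM (0.62), and genes are not independent replicates.

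**Figure D2:**
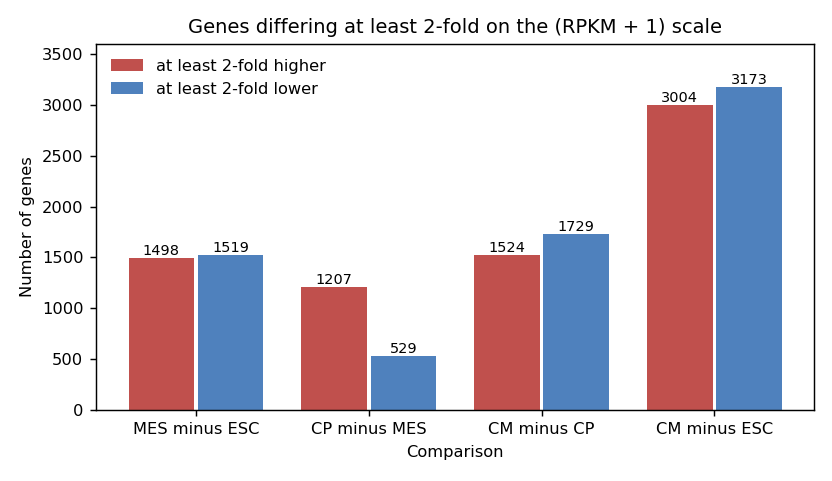
Number of genes (vertical axis) at least 2-fold higher (red bars) or lower (blue bars) on the log2(RPKM + 1) scale in each comparison of stages (horizontal axis). In CP against MES, 1207 genes are higher and 529 lower, while both numbers lie closer together in the other comparisons.

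The comparison of MES with ESC covers the exit from pluripotency and the formation of mesoderm. Pluripotency genes were far lower and primitive streak genes far higher in MES. Zfp42, also called Rex1 and a marker of naive pluripotency, stood at 251 RPKM in ESC and 0.758 RPKM in MES, a log2 difference of -7.17. Dppa5a, a pluripotency-associated gene, went from 321 to 1.93 RPKM and Tdh, the threonine dehydrogenase on which mouse ES cells depend, from 199.7 to 0.619 RPKM. Mesp1 was higher in MES by 7.05 on the log2 scale, the apelin receptor Aplnr by 6.30 (0.0788 to 84.1 RPKM) and the VEGF receptor gene Kdr by 5.56 (0.365 to 63.2 RPKM). The other genes with the largest differences were Foxf1a (0.20 to 89.9 RPKM), Hand1 (1.98 to 172 RPKM) and Cer1, a secreted NODAL and BMP antagonist listed at 0 in ESC and at 47.9 RPKM in MES. In the opposite direction stood Spp1, which encodes osteopontin (165 to 0.118 RPKM), the ribosomal protein gene Rpl10l (182 to 0.375 RPKM) and Lefty1, a NODAL antagonist (145 to 0.367 RPKM).

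Of 14 core pluripotency genes, 10 were at least 2-fold lower in MES and 0 higher, with a median log2 difference of -4.31. Utf1 went from 405 to 3.14 RPKM, Sox2 from 213 to 2.57 RPKM and Gdf3 from 52.6 to 0.228 RPKM, while Lin28a stood at 143 and 152 RPKM and Trim28 at 619.8 and 337 RPKM. Of 14 naive pluripotency genes, 13 were lower and 1, Tbx3, was higher (median -4.55). Among the lower genes were Fbxo15 (139 to 0.527 RPKM), Klf2 (165 to 0.996 RPKM) and Esrrb (85.2 to 0.194 RPKM). The 10 primed epiblast genes were divided, with 3 higher, 2 lower and 5 under 2-fold (median 0.10). Foxd3 stood at 20.7 and 0.755 RPKM, and Cdh2, the N-cadherin gene, at 2.05 and 35.0 RPKM. Of 22 primitive streak and early mesoderm genes, 17 were at least 2-fold higher in MES and 3 lower (median 3.13), and Lhx1 reached 42.9 RPKM from 0.0290 RPKM. Of 18 cardiac transcription factors, 10 were already higher in MES and 0 lower (median 1.75), including Hand2 (0.0653 to 30.8 RPKM) and Gata6 (0.152 to 28.7 RPKM). The sarcomere list lay near 0 (median -0.04), with 22 of 26 genes under 2-fold, and Myl7, the atrial myosin light chain, was among the exceptions at 4.27 RPKM in ESC and 68.1 RPKM in MES.

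Targets of WNT and BMP signalling were mostly higher in MES, and those of NODAL were divided. Of 9 WNT targets, 7 were higher in MES and 1 was lower (median 1.97), with Nkd1 at 1.06 and 47.7 RPKM, Dkk1 at 0.290 and 18.7 RPKM and Notum, the exception, at 32.4 and 2.34 RPKM. Of 9 BMP targets, 6 were higher and 0 lower (median 1.68), led by Msx1 (1.12 to 89.2 RPKM) and Msx2 (2.73 to 34.5 RPKM). The 8 NODAL and ACTIVIN targets were divided, with 3 higher and 3 lower (median -0.62), and Nodal itself stood at 42.4 and 2.74 RPKM. Endoderm markers were partly higher in MES as well, with 5 of 11 at least 2-fold higher and 0 lower (median 0.76), among them Cxcr4 (0.646 to 56.9 RPKM), Sox17 (0.104 to 9.34 RPKM) and Foxa2 (0.125 to 6.88 RPKM). Of 5 neural markers, 3 were lower and 1 higher in MES (median -1.55), with Tubb3 at 97.2 and 7.27 RPKM. The medians of both pluripotency lists lay below all 10000 random lists matched on mean expression, and those of the primitive streak, cardiac transcription factor, WNT and BMP lists above all of them.

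The comparison of CP with MES covers the entry into the cardiac lineage. Contractile genes, cardiac transcription factors and markers of endothelial and blood cells were higher in CP, and primitive streak genes were lower. Of 10 genes of dissociation and stress, 2 were at least 2-fold higher and 0 lower (median 0.35, at percentile 99.2 of the random lists). Tnnt2, cardiac troponin T, went from 0.116 to 437 RPKM, a log2 difference of 8.62, Tnnc1, troponin C, from 1.46 to 315 RPKM, and Smyd1, a muscle methyltransferase, from 0.0671 to 103 RPKM. Acta2, smooth muscle actin, which early cardiomyocytes also express, stood at 1.96 RPKM in MES and 498 RPKM in CP. The embryonic globin genes Hbb-bh1 and Hba-x reached 129 and 84.7 RPKM in CP, from 0.552 RPKM and a listed value of 0 in MES. Lower in CP were Mesp1, with a log2 difference of -6.87, Eomes, a T-box factor of the streak, with -6.09 (73.7 to 0.0929 RPKM), T with -5.55 and Evx1 with -5.03. Cer1 went from 47.9 to 0.0791 RPKM and Aldh1a2, which makes retinoic acid, from 45.2 to 0.307 RPKM.

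Of 26 sarcomere genes, 23 were at least 2-fold higher in CP and 0 lower (median 3.99), with Myh6 at 6.28 and Myh7 at 6.04 on the log2 scale, while Lmod2 and Myom2 stood at 0.0549 and 0.0924 RPKM in CP. Of 18 cardiac transcription factors, 13 were higher and 1, Hand1, was lower (median 2.02). Gata5 went from 0.503 to 84.2 RPKM, Myocd, the SRF coactivator myocardin, from 0.313 to 41.4 RPKM and Mef2c from 1.83 to 74.6 RPKM. Of 19 ion channel and calcium handling genes, 6 were higher and 1 was lower (median 0.53), among them Jph2 (0.561 to 82.6 RPKM), the pacemaker channel gene Hcn4 (0.791 to 33.6 RPKM) and the ryanodine receptor gene Ryr2 (0.191 to 11.02 RPKM). Nppa and Nppb, the natriuretic peptide genes, were still at 0.232 and 0.138 RPKM in CP. Of 22 primitive streak genes, 17 were lower in CP and 0 higher (median -2.59), with Kdr at 63.2 and 53.4 RPKM among those under 2-fold. Of 10 primed epiblast genes, 5 were lower (median -0.99). Of 9 WNT targets, 8 were lower and 0 higher (median -1.93), with Sp5 at 49.5 and 2.59 RPKM and Axin2 at 24.3 and 3.66 RPKM. Of 8 NODAL and ACTIVIN targets, 5 were lower and 0 higher (median -1.26).

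Markers of endothelial, blood and smooth muscle cells stood higher in CP beside the cardiac genes, while those of neural, endoderm and trophoblast cells were divided. Of 13 endothelial markers, 11 were at least 2-fold higher in CP and 1, Etv2, was lower (median 3.87). Cdh5, VE-cadherin, went from 0.215 to 71.3 RPKM, Cldn5 from 0.0457 to 48.5 RPKM, Sox18 from 0.349 to 62.1 RPKM and Tie1 from 0.108 to 50.1 RPKM. Of 13 blood markers, 11 were higher and 0 lower (median 2.46), including the transcription factor gene Lyl1 (0.458 to 17.1 RPKM) and Itga2b, which encodes CD41 (0.459 to 16.9 RPKM). Of 10 smooth muscle markers, 8 were higher and 0 lower (median 2.14), with Tagln at 2.26 and 43.2 RPKM and Cnn1 at 2.32 and 21.8 RPKM. Of 12 fibroblast and matrix genes, 5 were higher and 2 lower (median 0.67), and of 6 epicardial genes 3 were higher and 1, Aldh1a2, was lower (median 1.09). Of 5 neural markers, 1 was higher and 2 were lower (median -0.72), of 11 endoderm markers 5 were higher and 4 lower (median 0.27, or -0.28 over genes that reach 3 RPKM), and of 6 trophoblast markers 1 was higher and 1 lower (median 0.40). Of 4 skeletal muscle markers, 2 were higher and 0 lower (median 0.86), with Acta1 at 4.06 and Tnnt3 at 2.15 on the log2 scale. Acta1 went on from 24.4 RPKM in CP to 259 RPKM in CM, where most sarcomere genes were higher too, so its rise need not mark skeletal muscle cells. Values existed for 5 of 14 neural, 11 of 17 endoderm, 6 of 10 trophoblast and 4 of 13 skeletal muscle markers. These counts therefore cover only part of each list. The sarcomere, cardiac transcription factor, endothelial, blood and smooth muscle medians lay above all 10000 matched random lists. The primitive streak, primed epiblast, WNT, NODAL and cell cycle medians lay below all of these random lists. Gsc, Nodal and Lefty2 are in both the primitive streak and the NODAL list, so those medians are not independent. How many of the 1207 genes higher in CP owe their level to such cells cannot be read from bulk RNA.

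**Figure D3:**
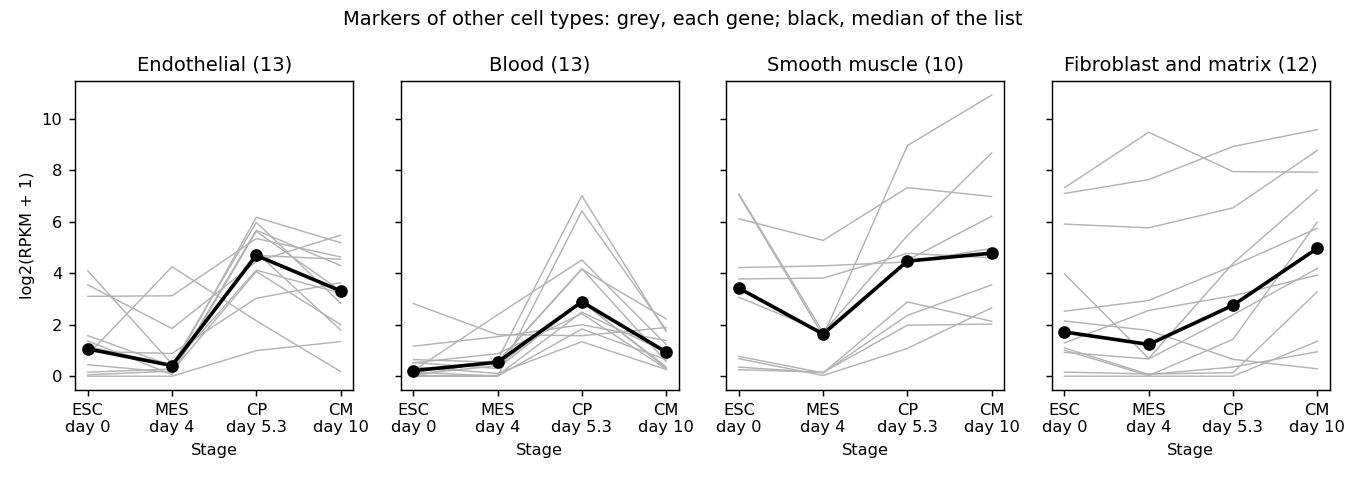
Log2(RPKM + 1) (vertical axis) of endothelial, blood, smooth muscle and fibroblast or matrix markers at the 4 stages (horizontal axis), with each gene in grey and the median of its list in black. The endothelial and blood medians are highest in CP, and those of the smooth muscle and matrix lists in CM.

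The comparison of CM with CP covers the step from precursors to cardiomyocytes. Genes of the contractile apparatus, of calcium handling and of energy metabolism were higher in CM, and cell cycle genes were lower. Genes of dissociation and stress, listed as a check of sample handling, were also higher, in 8 of 10 cases against 0 lower (median 1.75, above all 10000 matched random lists), with Fos at 50.3 and 176 RPKM, Junb at 38.9 and 168 RPKM and Hspb1 at 4.85 and 85.8 RPKM. Nppa, atrial natriuretic peptide, went from 0.232 to 693 RPKM, a log2 difference of 9.14, Nppb from 0.138 to 57.2 RPKM and the oxygen store myoglobin (Mb) from 0.515 to 112 RPKM. Actn2, the actinin of the Z-disc, stood at 8.11 RPKM in CP and 539.8 RPKM in CM. Igfbp7, which encodes a secreted IGF-binding protein, went from 0.254 to 269 RPKM and Gipr, the receptor of the gut hormone GIP, from 2.00 to 158 RPKM. Lower in CM were the WNT inhibitor gene Sfrp5 (89.8 to 0.0951 RPKM), Hbb-bh1 (129 to 2.32 RPKM), the imprinted gene Phlda2 (111 to 1.87 RPKM), the peptide YY gene Pyy (70.9 to 0.845 RPKM), the retinoic acid binding protein gene Crabp1 (182 to 3.72 RPKM) and Aplnr (42.9 to 0.466 RPKM).

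Of 26 sarcomere genes, 25 were at least 2-fold higher in CM and 0 lower (median 2.83), with Tnni3, cardiac troponin I, at 5.03 and 152 RPKM, the ventricular light chain gene Myl2 at 7.03 and 113 RPKM and Myh6 at 3.84 on the log2 scale. Tpm1, the remaining member, stood at 193 and 356 RPKM. Of 19 ion channel and calcium handling genes, 13 were higher and 1 was lower (median 1.85), among them phospholamban (Pln, 0.934 to 63.0 RPKM), triadin (Trdn, 0.0525 to 12.4 RPKM) and the sodium-calcium exchanger gene Slc8a1 (9.09 to 79.6 RPKM). All 5 natriuretic and secreted cardiac genes were higher (median 5.15), and Ankrd1 reached 544 RPKM from 14.3 RPKM. Of 17 genes of fatty acid and mitochondrial muscle metabolism, 15 were higher and 0 lower (median 1.91), including Cox6a2 (5.24 to 229 RPKM) and Pdk4 (0.572 to 24.4 RPKM). Glycolysis genes were also higher, with 9 of 16 at least 2-fold higher and 0 lower (median 1.15), among them Hk1 (8.64 to 82.5 RPKM), Pfkp (17.1 to 142 RPKM) and Aldoc (11.6 to 116 RPKM).

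All 22 cell cycle genes were at least 2-fold lower in CM (median -2.02), for example the replication licensing gene Mcm5 (99.6 to 8.10 RPKM) and Rrm2, a subunit of ribonucleotide reductase (41.4 to 4.49 RPKM). From MES to CP, 3 of these 22 genes were at least 2-fold lower and 19 differed by under 2-fold (median -0.68). The highest of the 22 stood at -0.11, and that median lay below all 10000 matched random lists. Of 18 cardiac transcription factors, 4 were higher and 7 lower in CM (median -0.35). Gata5 stood at 84.2 and 9.32 RPKM, Hand2 at 199 and 39.5 RPKM, Meis1 at 23.0 and 6.16 RPKM and Gata6 at 99.7 and 75.9 RPKM. Of 14 core pluripotency genes, 8 were lower in CM and 0 higher (median -1.47), with Lin28a at 113 and 2.94 RPKM. Of 14 naive pluripotency genes, 12 were under 2-fold, 1 was lower and 1, Esrrb, was higher (median -0.01), with Esrrb at 0.337 and 2.39 RPKM and Klf2 at 6.72 and 3.61 RPKM.

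Blood markers were mostly lower in CM than in CP, endothelial markers were in part lower, and matrix genes were mostly higher. Of 13 endothelial markers, 6 were at least 2-fold lower, 6 were under 2-fold and 1 was higher (median -0.99), with Tek at 27.1 and 2.49 RPKM and Cdh5 at 71.3 and 35.5 RPKM. Of 13 blood markers, 11 were lower and 0 higher (median -2.14), with Tal1 at 21.9 and 1.36 RPKM. Endoderm markers were lower in 6 of 11 cases and higher in 1 (median -1.01). Of 12 fibroblast and matrix genes, 7 were higher and 0 lower (median 1.41), led by the collagen genes Col3a1 (1.70 to 62.5 RPKM) and Col1a1 (19.9 to 151 RPKM) and by Postn (0.10 to 8.73 RPKM). Of 10 smooth muscle markers, 5 were higher and 0 lower (median 0.85), with Tagln at 408 RPKM and Acta2 at 1944 RPKM in CM. The sarcomere, ion channel, natriuretic, metabolic, glycolysis and matrix medians lay above all 10000 matched random lists. The cell cycle, blood, core pluripotency and anterior Hox medians lay below all of these random lists. The median of all genes was -0.15 in this comparison, a shift that the random lists share, and it was -0.21 with a pseudocount of 0.1 and -0.29 with each stage scaled to the same sum, which was tried after seeing the data and also lessens the weight of the pseudocount.

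**Figure D4:**
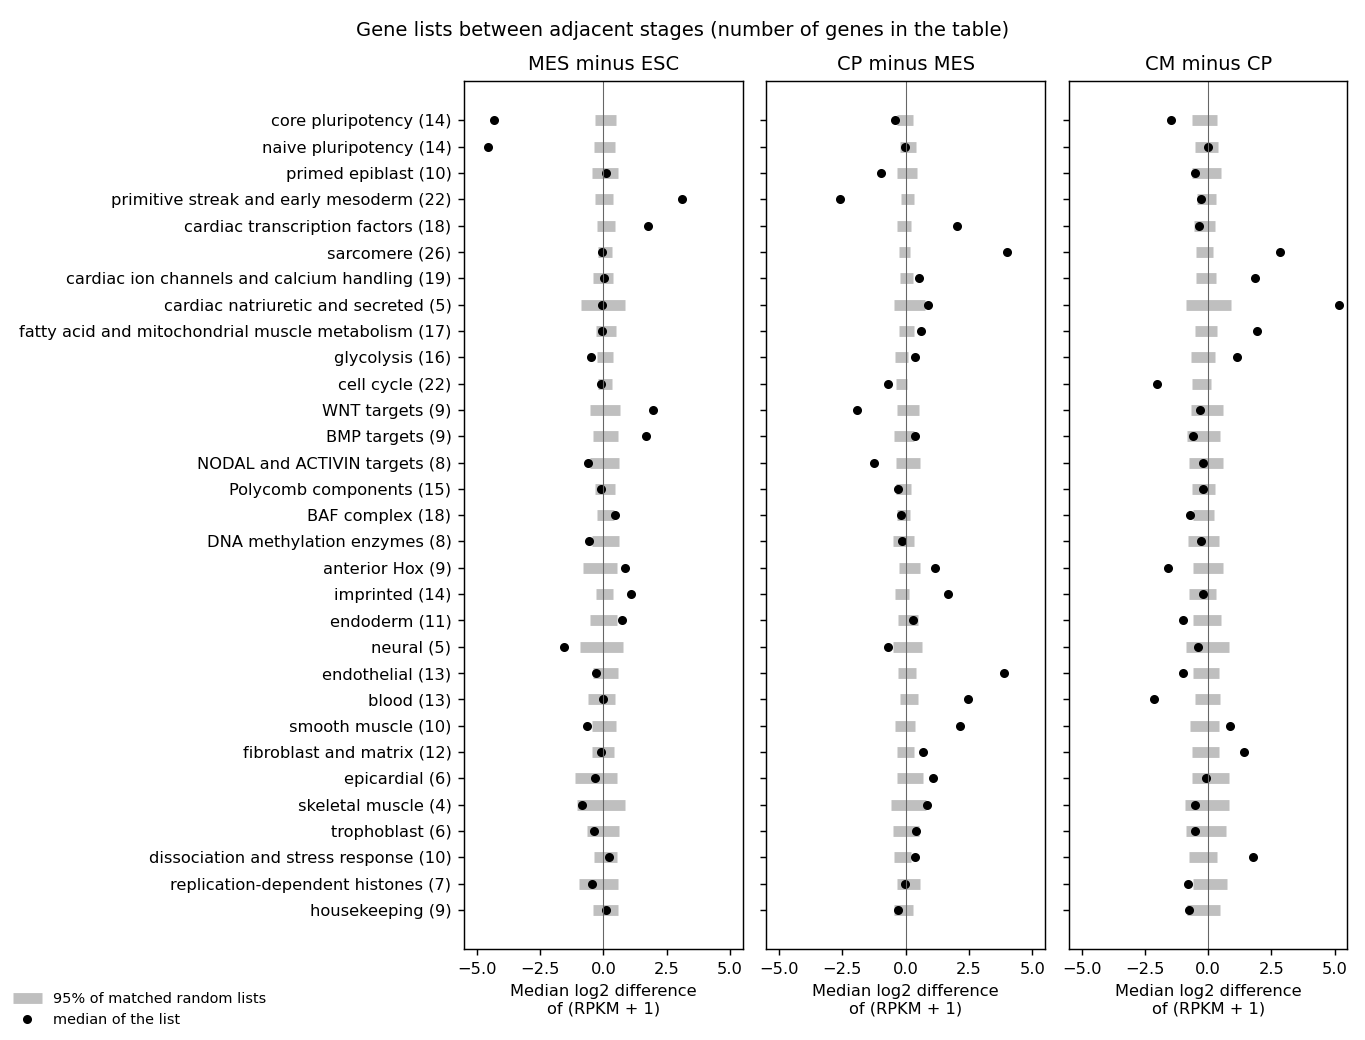
Median log2 difference of (RPKM + 1) (horizontal axis) of each gene list with at least 4 genes in the table (vertical axis, number of genes in parentheses) in the 3 comparisons of adjacent stages, as black points beside grey bars that span 95% of 10000 random lists matched on mean expression. The sarcomere list lies inside its bar from ESC to MES (-0.04) and far above it from MES to CP (3.99) and from CP to CM (2.83).

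Between both ends of the differentiation, 3004 genes were at least 2-fold higher in CM than in ESC and 3173 lower, a balance that also depended on the settings, with 1182 and 1050 at a minimum of 4-fold and 3206 and 3013 with each stage scaled to the same upper quartile, which was tried after seeing the data. All 26 sarcomere genes were higher in CM (median 6.69), with Actc1 at 9.71, Tnnt2 at 10.13, Myh6 at 8.54 and Myh7 at 9.42 on the log2 scale. Of 18 cardiac transcription factors, 17 were higher and 0 lower (median 4.10), with Nkx2-5 at 6.52, Gata4 at 5.40, Tbx5 at 4.29 and Isl1 at 3.74. All 14 core and all 14 naive pluripotency genes were lower (medians -5.65 and -4.32), with Pou5f1 at -9.33 and Nanog at -7.17. T stood at -2.19 and Mesp1, near its starting value, at -0.08. Markers of 3 other cell types were mostly higher in CM as well, in 10 of 13 endothelial (median 1.93), 7 of 10 smooth muscle (median 1.68) and 9 of 12 fibroblast and matrix cases (median 2.75), against 0, 0 and 1 lower. Of 13 blood markers, 4 were higher and 0 lower (median 0.36), and of 5 neural markers 0 were higher and 2 lower (median -0.62). Genes of dissociation and stress were higher in 8 of 10 cases and lower in 0 (median 2.35).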

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

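No paired analysis was possible because the table has 1 column per stage and carries no replicate number. For the same reason the planned limma variants, array weights, the replicate term, fits of only the stages compared, omission of single libraries, replicate agreement and other set tests were not run. The setting without a filter moved nothing, since every gene already passes 1 RPKM. All 335 results for named genes and all 49 list medians of at least 2-fold kept their direction under every alternative run, and 326 and 44 of them stayed at 2-fold or more. For single genes the direction was largely fixed in advance. Pseudocounts and filters cannot turn it, and a smaller pseudocount only enlarges a difference. Quantile normalization and the scalings were the alternatives that could turn it. Counted per result and alternative, whatever the size, 1244 named gene values moved beyond the 95% counting interval and 2845 did not. Of list medians, 185 moved by more than the SD of the random lists and 867 did not. Requiring 4-fold, which by construction keeps fewer genes, left 376 higher and 470 lower in MES than in ESC, 371 and 118 in CP against MES, 437 and 320 in CM against CP, and 1182 and 1050 in CM against ESC. It also left 3222 genes with such a range, 1039 of them highest in ESC, 481 in MES, 466 in CP and 1236 in CM. A pseudocount of 0.1, which shrinks differences at low values less, gave 2273 genes higher and 2103 lower in MES than in ESC, 1889 higher and 942 lower in CP than in MES, and 1937 and 2686 in CM against CP. Scaling to a sum of 1000000, added later, raises all values and so lessens the pseudocount, and gave 1818 genes higher in CP than in MES. The balance between CM and CP depended on the settings: quantile normalization gave 1683 genes higher and 1566 lower and upper-quartile scaling, added later, 1653 and 1556, while scaling to a sum of 1000000 gave 1674 and 2799. The sum scaling alters scaling and pseudocount at once, so its counts cannot be put down to either. The other near-even balances turned under some settings too. In MES against ESC, with 1498 higher and 1519 lower in the main setting, the sum scaling turned the balance to 2193 and 1893. Upper-quartile scaling kept its direction there, with 1371 higher and 1593 lower. In CM against ESC both scalings turned it, with 3606 higher and 3583 lower for the sum and 3206 and 3013 for the upper quartile. Depth limits low values most, and the spread between cultures stays unknown.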

Other observations

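Of the tests below, those of cytoskeletal genes against random lists and of shared sequence were written before their results were seen, and the others after. The condition that rho of the shared-sequence test must exceed its spread to count against the explanation was added after its value was seen.

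Imprinted genes were higher at each of the first steps. Of 14 such genes, 8 were at least 2-fold higher and 1 was lower in MES than in ESC (median 1.07), and 10 were higher and 1 was lower in CP than in MES (median 1.67). Both medians lay above all 10000 matched random lists. Between MES and CP, Dlk1 went from 1.65 to 158 RPKM, the noncoding RNA gene H19 from 8.46 to 112 RPKM and Igf2 from 107 to 1277 RPKM. Within these first steps, the Igf2 receptor gene Igf2r went from 27.3 to 235 RPKM. From CP to CM the list was divided, with 3 higher and 3 lower (median -0.19). Anterior Hox genes were higher in CP than in MES in 7 of 9 cases (median 1.16), and all 9 were lower in CM than in CP (median -1.59). Values existed for these 9 of the 16 anterior Hox genes listed. Hoxb1 stood at 0.189, 24.1, 14.6 and 0.0924 RPKM over the 4 stages and Hoxb4 at 0.106, 0.340, 4.46 and 0.899 RPKM. Of the posterior Hox list, Hoxd9 alone was in the table, at 1.49 RPKM in CP.

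Chromatin regulators differed by member. Of 8 DNA methylation enzymes, 5 were lower and 1 was higher in CM than in ESC (median -2.39). Dnmt3l, a cofactor of de novo methylation, stood at 90.5 RPKM in ESC and 0.337 RPKM in MES, and Dnmt3b at 81.4, 51.6, 24.6 and 0.807 RPKM. Tet1 went from 59.98 to 8.48 RPKM between ESC and MES while Tet3 went from 1.84 to 7.96 RPKM. Of 15 Polycomb components, 5 were higher and 4 lower in MES than in ESC (median -0.09), with Cbx7 at 70.3 and 3.68 RPKM and Cbx2 at 7.74 and 48.0 RPKM. Of 18 genes of the BAF remodelling complex, 5 were higher and 0 lower in MES (median 0.47), and 8 were lower and 0 higher in CM than in CP (median -0.72). Smarcd3, the heart-enriched BAF60c subunit, stood at 1.25, 13.9, 41.7 and 18.1 RPKM. Of 9 housekeeping genes, 1 was higher and 3 lower in CM than in CP (median -0.76), with Polr2a at 59.0 and 22.9 RPKM. The 7 replication-dependent histone genes had a median of -0.81 there, or 0.36 over those that reach 3 RPKM, and poly(A) libraries hold few of their transcripts. In MES against ESC the skeletal muscle (4 genes) and trophoblast (6 genes) medians were -0.84 and -0.37.

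The smooth muscle genes Acta2 and Tagln were lowest in MES, while of the 10 genes of their list 3 were lower, 0 higher and 7 under 2-fold in MES against ESC (median -0.65). Acta2 stood at 131 RPKM in ESC, 1.96 in MES, 498 in CP and 1944 in CM, and Tagln at 134, 2.26, 43.2 and 408 RPKM. Carry-over of cardiomyocyte RNA into ESC libraries is argued against, since it would bring sarcomere transcripts at a like share: the ESC level of Acta2 was 6.76% of its CM level, and the median over the sarcomere list was 0.194%, although 2 of its 26 genes lay above the Acta2 percentage, the highest at 18.9%. Fibroblasts such as feeder cells in the ESC cultures stay open, because the fibroblast list had a median of -0.11 in MES against ESC with members on both sides. Of its 4 collagen genes, 1 was higher in MES than in ESC, and Col1a1 stood at 14.8 RPKM in ESC and 0.615 RPKM in MES. A cytoskeletal response to adherent culture in ESC and CM against suspended aggregates in MES is a candidate explanation, although how the ESC were grown is not given in the sources used here. A list of 24 other actin cytoskeleton and SRF or YAP target genes, added after this was seen and chosen without their values, had a median of -0.91 in MES against ESC, at percentile 0 of the 10000 random lists (12 lower, 2 higher). Fibroblasts, which express many of these genes, could give the same result. From MES to CP, 8 of the 24 were higher and 0 lower (median 0.78). From CP to CM, 10 were higher and 2 lower (median 0.87). Sarcomere and smooth muscle medians were also higher at both of these later steps, so those steps cannot separate the explanations.

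Endothelial and blood markers were highest in CP as groups. A lower share of the main cell type in CP, which would raise the other cell types present, cannot be judged from these lists. The 15 neural, trophoblast and skeletal muscle genes had a median of 0.29 in CP against MES, while the endothelial median was 3.87. The difference was 3.58 (bootstrap over genes, 1.74 to 5.96), so these markers did not rise alike. That interval covers the spread among genes and not between cultures, and the endothelial list was taken after its rise was seen. Values existed for only 5 of 14 neural, 6 of 10 trophoblast and 4 of 13 skeletal muscle markers. Such cells may therefore be missing from the cultures, and a lower share could not raise them. The 4 skeletal muscle genes among the 15 had a median of 0.86, at percentile 98.0 of the random lists. Hand1 is also in the cardiac list, and Acta1 was higher again in CM. Endothelial and blood progenitor cells in the CP cultures stay open and were not tested on other genes: both list medians lay at percentile 100 of the random lists, which restates the pattern. Bulk RNA does not separate such cells from cardiac precursors that express some of these genes, and no sorting step is given in the sources used here.

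Gapdh stood at 12.7, 9.19, 9.13 and 8.61 RPKM and Ppia at 5.09, 5.46, 3.25 and 1.37 RPKM, low beside Aldoa at 322 RPKM in ESC (these 3 genes were chosen after their values were seen). Reads shared with near-identical copies and not counted could lower such genes. Over 24 glycolysis and housekeeping genes, which are not independent replicates, Spearman's rho between shared sequence and mean log2(RPKM + 1) was 0.0684 (permutation p = 0.752, two-sided) and Pearson's r 0.0225 (permutation p = 0.909), or 0.191 without the 2 genes farthest from the median. The 2 genes with over 50% shared words had a median of mean RPKM of 25.7, against 55.8 for the 22 others, too few for a comparison. Gapdh and Ppia, at 31.6% and 25.05%, were among the 22. The bound set beforehand against this explanation, a rho of 0 or more, was met, but by less than the spread of rho over permutations. The explanation stays open for that reason, and because words came from the longest transcript only, which can understate sharing. The search also covered annotated transcripts only, not unannotated copies in the genome. No biological explanation was tested.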
